A study of Mus musculus with 16 samples.

How the data were processed

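The 16 libraries came from male mice with extra LTA4H in their adipocytes (OE) and their control mice (Ctrl). LTA4H, leukotriene A4 hydrolase, makes the lipid mediator leukotriene B4. The labels do not name the promoter that drives the extra gene, and they give no sequencing batch. Total RNA from epididymal white adipose tissue, the visceral fat pad beside the epididymis, was isolated with RNeasy and made into stranded mRNA libraries with the TruSeq kit.

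Per the submitters' processing notes, the authors used bcl2fastq 2.20.0, Trimmomatic (version not stated), HISAT2 2.1.0 and StringTie 2.1.3b on the mouse genome build mm10. The strand setting of the counting and the annotation release were not stated. The deposited read counts, whole numbers for 45,777 genes that the authors had not normalised, were the values tested. StringTie derives counts from coverage, so the authors' read counts may be rounded estimates. The authors' FPKM values (fragments per kilobase, scaled to library depth) were not tested. The authors' TPM values (per kilobase, scaled to the same sum in each library) were not tested either.

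Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes were kept with filterByExpr at a minimum count of 10, which left 19,189 genes, and libraries were scaled by TMM. A robust quasi-likelihood fit held all 4 groups of 4 libraries, with 12 residual degrees of freedom, and 6 contrasts were tested. P-values were adjusted by Benjamini-Hochberg over all genes tested, and a gene was called at an adjusted p under 0.05. Unless another tool is named, adjusted p-values of genes are from this fit. Errors of log2 fold changes are standard errors from the fit. CPM are counts scaled to library size with TMM factors (CPM in edgeR), given as mean ± SD or per library. Log2 CPM for list means and principal components used a prior count of 2. Positions are on mm10 and come from the RefSeq annotation by gene ID.

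Gene lists for adipose cell types, lipid metabolism, leukotrienes, inflammation, matrix, stress and tissue admixture, 33 in all with 616 members of which 1 was not in the table, were fixed before the data were examined, as were the contrasts, the filter, the alternative settings not said to be added later and the rule for naming genes. Lists were tested with camera (limma 3.58.1) at a preset correlation of 0.01, again with the correlation estimated for each list, and with fry, each adjusted over the 33 lists. Camera compares a list with the other genes, whereas fry asks whether its members move one way on balance.

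Genes are named by the following rule. Lta4h came first. Then, for each contrast, came the 10 rising and the 10 falling genes with the largest fold change among called genes with a mean log2 CPM of at least 1, no overlap between the groups and a symbol that is not a predicted or clone name. For the interaction and the average the overlap was not asked for. For each list with a called member, up to 4 called members with the smallest adjusted p followed, and leukotriene list members were named in any case. Where under 6 genes were called, the 10 with the smallest p were named with their values. Only a part of these genes is printed.

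DESeq2 1.42.0, limma voom with sample quality weights, and surrogate variables from sva 3.50.0 served as alternatives. Sequence similarity was searched with BLAST 2.17.0 at a word size of 20 and an E-value limit of 1e-10. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.

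Counts simulated from the measured means, library sizes and dispersions, with 200 genes changed, tested the fit. For OE against Ctrl at 8 weeks, 12.5% of changes of 1.5-fold, 51.7% of 2-fold and 71.4% of 4-fold were recovered, with 2.15% false among called genes. For OE against Ctrl at 20 weeks the shares were 16.7%, 50% and 64.5%, with 4.44% false. For 20 against 8 weeks in Ctrl they were 22.9%, 46.8% and 64.7%, with 3.13% false. For 20 against 8 weeks in OE they were 23.3%, 46.8% and 69.8%, with 6.80% false. In each of these 4 simulations a list shifted 1.5-fold was called and 0 of 33 unchanged lists were called by camera. Genes were simulated independently and lists were drawn at random, so this does not show how often camera calls lists of correlated genes.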

Results

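RNA from epididymal white adipose tissue was sequenced in 4 groups of 4 male mice each. OE and Ctrl mice received a high-fat diet from 4 weeks of age, and tissue was taken after 4 weeks of diet, at 8 weeks of age, or after 16 weeks, at 20 weeks of age. Total counts, in M (mega, 10 to the power of 6), ranged from 33.6 to 67.6 M per library. At 20 weeks they were 33.6, 36.5, 38.4 and 35.7 M in Ctrl replicates 1 to 4 and 40.3, 40.4, 37.9 and 44.5 M in OE. At 8 weeks they were 40.9, 49.3, 44.6 and 67.6 M in Ctrl and 43.9, 34.2, 36.1 and 45.4 M in OE.

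The first principal component held 55.8% of the variance and the second 13.9%. OE_20wk replicate 1 lay at 22.4 on the first component, whereas the other 20-week libraries lay between −96.6 and −66.7. Its macrophage list mean was 6.45 log2 CPM against 7.01 to 7.47 in the other 20-week libraries, and its mature adipocyte list mean was 10.05 against 8.56 to 9.49. Ctrl_8wk replicate 1 and OE_8wk replicate 1 stood apart together on the second component, at −94.2 and −91.8, and lay at −29.9 and −19.5 on the first, where the other 8-week libraries lay between 68.8 and 125. Ctrl_8wk replicate 4 and OE_8wk replicate 2 held transcripts of the epididymal duct, with summed CPM of 3678 and 2420 over the epididymal epithelium list against at most 166 in any other library. The same pair had the highest smooth muscle list means, at 7.77 and 7.83 log2 CPM against at most 6.49 elsewhere.

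The comparison of OE with Ctrl at 8 weeks asked what the extra LTA4H does to the fat pad early in the diet. Lta4h (gene ID 16993, chromosome 10, 93453396 to 93484896) had 353 ± 77.9 CPM in OE (SD, n = 4) and 89.7 ± 10.5 CPM in Ctrl (SD, n = 4). It was 3.94-fold higher, a log2 fold change of 1.98 ± 0.14 with an adjusted p of 2.08e-05. All 4 OE libraries, at 251 to 427 CPM, lay above all 4 Ctrl libraries, at 79.4 to 104 CPM (two-sided exact permutation p = 0.0286, the smallest that 4 against 4 allows). The other genes of leukotriene synthesis and response were not called, with log2 fold changes of 0.04 ± 0.13 for Alox5, the 5-lipoxygenase, and 0.14 ± 0.22 for Alox5ap, its activating protein. They were −0.17 ± 0.30 for Ltc4s, the leukotriene C4 synthase, 0.07 ± 0.26 for Ltb4r1, the high-affinity leukotriene B4 receptor, and 0.19 ± 0.16 for Cysltr1, a cysteinyl leukotriene receptor.

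Beside Lta4h, 3 genes were called at 8 weeks, each higher in OE. The pseudogene Gm11868 (ID 667251, chromosome 4, 18844005 to 18845867) had 2.94 CPM in OE and 0.141 in Ctrl, a log2 fold change of 4.39 ± 0.35 (adjusted p = 3.40e-05). The transcribed pseudogene Morf4l1-ps1 (ID 624582, chromosome 16, 24529314 to 24534472) differed by 0.80 ± 0.08 (adjusted p = 2.60e-04). Morf4l1b (ID 627352, chromosome 19, 41525252 to 41526961), a gene copy related to the chromatin factor Morf4l1, differed by 0.61 ± 0.07 (adjusted p = 0.00426), and was not called when only the 2 groups compared were fitted (0.149), with glmTreat at 1.2-fold (0.152), without the libraries numbered 1 at 8 weeks (0.143) or without these and OE_20wk 1 (0.142). No gene was lower with edgeR, while DESeq2 called 10 higher and 5 lower and voom 10 higher and 2 lower; 424 genes had an unadjusted p under 0.05. Among the 10 smallest p-values but not called were Eif4a2, a translation initiation factor (0.70 ± 0.12, adjusted p = 0.124), the ribosomal protein gene Rpl29 (−0.87 ± 0.15, 0.124), the zinc finger gene Zfp949 (1.12 ± 0.20, 0.145) and the pseudogenes Gm13841 (3.09 ± 0.62) and Gm8210 (3.95 ± 0.79), each at 0.359. Without OE_20wk replicate 4, 8 genes were higher and 1 lower, and the calls then took in Rpl29 (3.69e-04) and both pseudogenes (1.50e-09 each). Eif4a2 was called without Ctrl_8wk replicate 4 (0.0229) and Zfp949 without OE_8wk replicate 2 (0.0289).

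Among the fixed lists, Lta4h was the only member called at 8 weeks, over all genes and also when adjusted over the list alone, where the leukotriene list had 1 of 19 higher. Camera called 14 of the 33 lists, 8 higher and 6 lower. The leukotriene list, which holds Lta4h, had an adjusted p of 7.08e-08, and 0.00115 with an estimated correlation. The cholesterol synthesis list had a mean log2 fold change of −0.29 (5.70e-11, and adjusted p = 0.296 with an estimated correlation). The macrophage list had a mean of 0.27 (1.73e-05, and 0.689 with an estimated correlation), and the lipid-associated macrophage list 0.55 (3.93e-04, and 0.689). Without OE_8wk replicate 2 the means of these 2 lists were 0.0941 and −0.0169. Of the 14 lists the leukotriene list alone was called with an estimated correlation, and fry called 1 list. The number of lists called by camera was 9 without Ctrl_8wk replicate 2 and 7 without OE_8wk replicate 2.

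**Figure D1:**
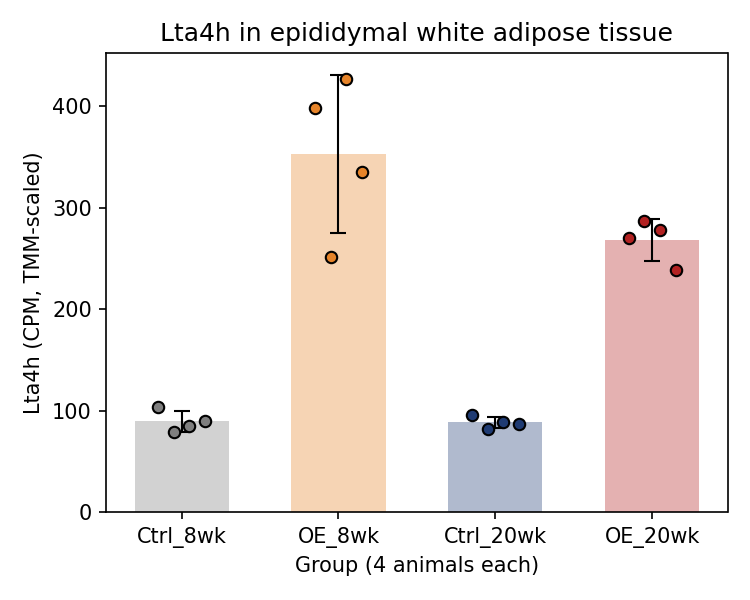
Lta4h CPM on a linear axis from 0 in each of the 16 libraries by group, with the mean and SD of each group of 4. OE libraries lie at 251 to 427 CPM at 8 weeks and 239 to 286 at 20 weeks, and Ctrl libraries at 79.4 to 104 and 82.4 to 95.4.

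The comparison of OE with Ctrl at 20 weeks asked the same of established obesity. Lta4h had 268 ± 20.8 CPM in OE (SD, n = 4) and 88.5 ± 5.37 CPM in Ctrl (SD, n = 4), 3.03-fold higher, with a log2 fold change of 1.60 ± 0.14 (adjusted p = 1.45e-04). The OE libraries, at 239 to 286 CPM, all lay above the Ctrl libraries, at 82.4 to 95.4 CPM (two-sided exact permutation p = 0.0286, the smallest possible). Other leukotriene genes were not called, with −0.15 for Alox5, −0.07 for Alox5ap, 0.15 for Ltc4s, −0.24 for Ltb4r1 and 0.12 for Cysltr1. Gm11868 (4.17 ± 0.34, adjusted p = 1.06e-04) and Morf4l1-ps1 (0.69 ± 0.08, 0.00167) were higher again. Zfp949 (ID 71640, chromosome 9, 88548020 to 88571086) had 25.5 CPM in OE and 9.20 in Ctrl, a log2 fold change of 1.47 ± 0.20 (0.0142). The pseudogene Gm7049 (ID 630951, chromosome 13, 62812916 to 62815515) was higher by 2.79 ± 0.42 (0.0432). Morf4l1b, at 0.46 ± 0.07, was not called (0.0649).

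No gene was lower at 20 weeks with edgeR, while DESeq2 called 40 higher and 20 lower and voom 14 higher and 6 lower; 762 genes had an unadjusted p under 0.05. Values not called included the immunoglobulin segment Igkv4-55 (−4.43 ± 0.82, adjusted p = 0.239), the neuronal adhesion gene Nrcam (−1.03 ± 0.20), the galectin gene Lgals7 (−1.78 ± 0.36) and Lysmd2 (0.80 ± 0.16), the last 3 at 0.386. Igkv4-55 rested in part on Ctrl_20wk replicate 1, with 49.9 CPM against 3.46 to 9.04 in the other Ctrl libraries. Zfp949 was not called without Ctrl_20wk replicates 1, 2 or 3 or OE_20wk replicates 1, 2 or 3, with adjusted p from 0.0589 to 0.105. Gm7049 was not called without Ctrl_20wk 1, 2 or 3, OE_20wk 1, 2 or 3, Ctrl_8wk 1, 2 or 3 or OE_8wk 1, 3 or 4, with 0.0608 to 0.209. Gm7049 was also lost with only the 2 groups compared, with the replicate block, with glmTreat at 1.2-fold and without the libraries numbered 1 at 8 weeks. Without these and OE_20wk 1 both Gm7049 and Zfp949 were lost. The count of higher genes was 3 without Ctrl_20wk 2 or 3 or OE_20wk 1, 2 or 3, and 1 gene was lower without Ctrl_20wk 1 or 4, Nrcam among them without Ctrl_20wk 4 (0.0388).

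At 20 weeks 3 cell type lists held members that passed when adjusted over the list alone, though 0 passed over all genes. Of the B and plasma cell list 10 of 17 were lower by that measure, of the mast cell list 5 of 10 and of the mesothelial list 7 of 12. Their median log2 fold changes were −1.74, −1.06 and −0.96. Camera gave adjusted p-values of 6.89e-18, 3.52e-11 and 1.58e-14, which became 0.199, 0.199 and 0.127 with an estimated correlation. The mature adipocyte list had a median of 0.38 (1.21e-07, and 0.385 with an estimated correlation) and the cholesterol synthesis list 0.32 (6.17e-09, and 0.323). The leukotriene list had 1 of 19 higher, Lta4h, adjusted over all genes or over the list alone, with a camera adjusted p of 0.191. Camera called 13 lists, 7 higher and 6 lower, of which 0 were called with an estimated correlation and 0 by fry. The mast cell and mesothelial lists each held a library far from the other 3, Ctrl_20wk replicate 4 at 2.90 log2 CPM against 3.98 to 4.05 and OE_20wk replicate 3 at 2.12 against 3.24 to 3.39. The B and plasma cell list had a mean log2 fold change of −1.75, and −0.81 without Ctrl_20wk replicate 1, which lay at 4.75 log2 CPM against 2.16 to 2.95 in the other Ctrl libraries. The mesothelial mean was −0.78, and −0.49 without Ctrl_20wk replicate 4, and the mature adipocyte mean was 0.42, and 0.17 without OE_20wk replicate 1.

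Averaged over both ages, 7 genes were higher in OE and 0 lower with edgeR, 389 having an unadjusted p under 0.05, while DESeq2 called 30 higher and 3 lower and voom 10 and 0. Lta4h was higher by 1.79 ± 0.10 (adjusted p = 3.90e-07), beside Gm11868, Morf4l1-ps1, Morf4l1b (0.53 ± 0.05, 2.86e-04), Zfp949 (1.30 ± 0.14, 7.80e-04) and Gm7049. Eif4a2 (ID 13682, chromosome 16, 23107468 to 23114132) was higher by 0.60 ± 0.08 (0.0122) but was not called without Ctrl_20wk replicate 2 (0.0509) or 3 (0.0510), with the replicate block (0.101), with glmTreat at 1.2-fold (0.255), without the libraries numbered 1 at 8 weeks (0.0670) or without these and OE_20wk 1 (0.175). Without OE_20wk replicate 4, 1 gene was lower. Camera called 8 lists, and 1, the leukotriene list, was called with an estimated correlation (0.00280) and by fry. That list holds Lta4h, raised by design, and was not tested without it. Without OE_20wk replicate 2 camera called 13 lists and without Ctrl_8wk replicate 2 it called 14.

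The interaction of genotype and age tested whether the difference between OE and Ctrl changed from 8 to 20 weeks. For Lta4h it was −0.38 ± 0.19 (unadjusted p = 0.0737 and adjusted p = 0.982 with edgeR). With edgeR 0 genes were called in either direction, 650 having an unadjusted p under 0.05, while DESeq2 called 20 higher and 10 lower, voom 0 in either direction, and edgeR 3 lower without OE_20wk replicate 4. The smallest p-values belonged to Gpr34, a microglial and macrophage receptor (−1.11 ± 0.21), the adhesion receptor gene Adgrd1 (−0.86 ± 0.17), the transcription factor gene Bhlhe40 (1.18 ± 0.24), Nrcam (−1.36 ± 0.29) and Usp10 (0.38 ± 0.08), each with an adjusted p of 0.982 and not called. Adjusted over the list alone, 7 of 17 B and plasma cell genes and 8 of 12 mesothelial genes were lower and 2 of 23 cholesterol synthesis genes higher. Camera called 19 lists and 0 with an estimated correlation (lowest adjusted p 0.124), fry called 0, and camera called 11 without OE_20wk replicate 1. The leukotriene list's median was −0.19 and its mean 0.38 while camera placed it lower (0.0433, and 0.183 with an estimated correlation).

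Across genes, the genotype effect at 8 weeks did not follow that at 20 weeks. Pearson's r was −0.0789 and Spearman's rho −0.187 over 19,189 genes, which are not independent replicates. Without Ctrl_20wk replicate 1 r was −0.209, without OE_8wk replicate 4 it was −0.233, without Ctrl_8wk replicate 3 it was 0.0434 and without OE_8wk replicate 1 it was 0.0168. The genes called higher at both ages were 3, Lta4h, Gm11868 and Morf4l1-ps1.

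The comparison of 20 with 8 weeks in Ctrl asked what longer high-fat feeding, and with it age, does to the fat pad. Macrophage transcripts linked to lipid uptake were among the largest rises. Gpnmb, a glycoprotein of lipid-laden macrophages (ID 93695, chromosome 6, 49036518 to 49058182), rose by a log2 fold change of 6.27 ± 1.01. Trem2, a lipid-sensing receptor (ID 83433, chromosome 17, 48346401 to 48352276), rose by 5.20 ± 0.61, and the integrin gene Itgad by 5.88 ± 0.54 (n = 4 in each group). Adipocyte products fell, among them Cfd, the adipokine adipsin (ID 11537, chromosome 10, 79890853 to 79892655), 20.3-fold lower, and Cyp2e1, a cytochrome P450, 19.6-fold lower. For each of these genes all 4 libraries of one age lay outside the range of the other.

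Of 19,189 genes, 3770 rose and 4083 fell in Ctrl, 40.9% in all, with 1704 and 1964 changing more than 2-fold. With 2 surrogate variables 1083 rose and 675 fell, and of 158 named gene results 72 lost their call and 1, Alox12, reversed. Among the genes given here and below that setting lost Dsp, Gstm7, Cnn1, Cd79b, Itgae, Cox6c, Ndufa4, Irs1, Pmvk, Rgs5, Notch3, Hbb-bs, Hbb-bt, Tgfb1, Cxcl16, Ccl9, Alox5ap, Ltb4r1, Cysltr1, Mgst3 and Ggt1. Other large rises were the myosin gene Myh15 (6.69 ± 1.07), the proton pump subunit gene Atp6v0d2 (5.72 ± 0.92), the orphan receptor gene Gpr50 (5.44 ± 0.73), the serotonin receptor gene Htr2b (5.44) and Rgs1 (5.42). Other large falls were Serpina3b (−4.33 ± 0.68), the acute-phase gene Orm3 (−4.21 ± 0.41), the desmosome gene Dsp (−5.23 ± 1.33) and Gstm7 (−4.57 ± 1.14). The last 2 were uneven at 8 weeks, with 1.99 and 7.38 CPM in Ctrl_8wk replicate 1 against 11.1 to 53.7 and 37.1 to 108 in the other Ctrl libraries of that age. The smooth muscle genes Cnn1 (−7.56 ± 2.02) and Myh11 (−4.30 ± 1.14) fell too, but by −4.44 and −2.31 without Ctrl_8wk replicate 4, a library with epididymal transcripts. The number of falling genes was 2685 without Ctrl_20wk replicate 2 and 2518 without Ctrl_20wk replicate 3. Lta4h itself did not pass in Ctrl (−0.02 ± 0.14, adjusted p = 0.927). Age, diet duration and any processing batch that followed age cannot be told apart.

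Several immune cell lists moved upward in Ctrl. In the macrophage list 16 of 20 members rose and 1 fell (16 and 3 adjusted over the list alone), such as Cd68 (3.58 ± 0.41), C1qc (2.15 ± 0.23) and C1qb (2.21 ± 0.24). In the lipid-associated macrophage list 15 of 17 rose and 1 fell (15 and 1 adjusted over the list alone), with a median of 3.06, such as the protease gene Ctsk (2.75 ± 0.27), the adaptor gene Tyrobp (2.79 ± 0.30) and the acid lipase gene Lipa (3.06 ± 0.34). Camera gave 3.03e-12 and 5.47e-15 for the 2 lists, each 0.347 with an estimated correlation, and fry 1.87e-04 for each. In the mast cell list 8 of 10 rose and 0 fell by either adjustment, among them Mcpt4 (3.13 ± 0.38) and Tpsb2 (3.32 ± 0.45), with 1.41e-06 by camera and 0.518 with an estimated correlation. In the B and plasma cell list 13 of 17 rose and 1 fell (15 and 1 adjusted over the list alone), with a median of 2.21, including Cd22 (3.96 ± 0.51) and Cd79b (1.89 ± 0.43, but 1.17 without Ctrl_20wk replicate 1). In the T cell list 4 of 20 rose by either adjustment, including Il7r (4.24 ± 0.56) and Cd28 (1.69 ± 0.31), and 16 did not pass. Of the dendritic cell list 8 of 15 rose and 2 fell (10 and 2 adjusted over the list alone), with Cd83 at 2.60 ± 0.28 and Irf8 at 1.55 ± 0.23 among the rises and the integrin gene Itgae at −1.50 ± 0.25 among the falls. These 3 lists had camera adjusted p-values of 0.00455, 0.0389 and 0.0423, which were 0.594, 0.625 and 0.543 with an estimated correlation.

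The adipocyte and metabolic lists that camera called in Ctrl moved downward. Of the mature adipocyte list 13 of 20 fell and 0 rose (15 and 0 adjusted over the list alone), with a median of −1.10. Examples were Retn, which encodes resistin (13.5-fold lower), the adipogenic regulator Pparg (−1.13 ± 0.16) and Slc2a4, the insulin-responsive glucose transporter (−2.16 ± 0.33). Of fatty acid and triglyceride synthesis 17 of 22 fell and 0 rose (19 and 0 adjusted over the list alone), among them Thrsp (−2.32 ± 0.35) and the desaturase gene Scd1 (−2.23 ± 0.34). Of nuclear oxidative phosphorylation genes 23 of 35 fell and 0 rose (27 and 0 adjusted over the list alone), by modest amounts, as in Cox6c (−0.54 ± 0.09) and Ndufa4 (−0.55 ± 0.12). Camera gave 2.01e-08, 1.41e-06 and 3.29e-06, and 0.543, 0.543 and 0.582 with an estimated correlation. Of the insulin signalling list 10 of 19 fell, Irs1 (−1.30 ± 0.24) among them, and 4 rose by either adjustment (camera 0.0467, and 0.543 with an estimated correlation). Of the cholesterol synthesis list 9 of 23 fell and 1 rose by either adjustment, with Fdft1 at −0.92 ± 0.13 and Pmvk at −1.13 ± 0.27 (camera 0.0307, and 0.594 with an estimated correlation).

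Vascular lists fell and proliferation genes rose in Ctrl. All 28 proliferation genes tested rose by either adjustment, with a median of 1.48, such as Pcna (1.44 ± 0.17) and Mcm6 (1.53 ± 0.20), at 1.82e-18 by camera and 0.518 with an estimated correlation. Of the endothelial list 12 of 15 fell and 0 rose by either adjustment, such as Erg (−0.90 ± 0.15) and Robo4 (−0.91 ± 0.17). Of the smooth muscle and pericyte list 9 of 12 fell and 2 rose (10 and 2 adjusted over the list alone), with Rgs5 at −1.28 ± 0.20 and Notch3 at −0.58 ± 0.13, and with Acta2 at −2.16 ± 0.49, or −1.51 without Ctrl_8wk replicate 4. All 6 erythroid genes fell by either adjustment, among them the globin genes Hbb-bs (−2.72 ± 0.49) and Hbb-bt (−2.78 ± 0.50). Camera gave 3.59e-05, 0.0117 and 6.07e-05 for these 3 lists, each 0.543 with an estimated correlation. Of the extracellular matrix list 12 of 31 rose and 1 fell (12 and 2 adjusted over the list alone), with the metalloproteinase genes Mmp2 (1.71 ± 0.20) and Mmp14 (1.49 ± 0.18). Of chemokines and cytokines 14 of 34 rose and 2 fell by either adjustment, with Tgfb1 (1.38 ± 0.21), Cxcl16 (1.41 ± 0.26) and Ccl9 (2.11 ± 0.41). Camera gave 0.00145 and 0.0119, and 0.543 for each with an estimated correlation. Camera called 18 lists in Ctrl, 10 higher and 8 lower, 0 of them with an estimated correlation, while fry called 22.

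Leukotriene genes went both ways in Ctrl, with 4 of 19 higher and 4 lower by either adjustment and a camera adjusted p of 0.566. Dpep2, which converts leukotriene D4 to E4, rose by 3.22 ± 0.38, Alox5ap by 1.12 ± 0.22, Ggt5, which converts leukotriene C4 to D4, by 0.79 ± 0.13 and Cysltr1 by 0.55 ± 0.16. Ltb4r1 fell by 1.27 ± 0.26 and Mgst3, a microsomal glutathione transferase, by 0.85 ± 0.23. Alox12, the 12-lipoxygenase, fell by 2.69 ± 0.99, and Ggt1 had 0 CPM in all 4 libraries at 20 weeks against 0, 10.8, 35.3 and 25.0 CPM at 8 weeks. Cysltr1 was not called without Ctrl_8wk replicate 3 (0.0518). Alox12 was not called without any one of Ctrl_20wk 1 to 4, OE_20wk 3 or Ctrl_8wk 2, 3 or 4 (0.0503 to 0.105), nor Ggt1 without any one of Ctrl_20wk 1 to 4 or Ctrl_8wk 3 (0.0540 to 0.0645). Without both libraries with epididymal transcripts neither Alox12 (0.0801) nor Ggt1 (0.0543) was called. Like Ggt1, Alox12 was lowest in Ctrl_8wk replicate 1 at that age in Ctrl, with 1.01, 6.41, 15.5 and 11.7 CPM in replicates 1 to 4. Whether these 2 falls reflect other tissue in the 8-week samples was not tested.

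**Figure D2:**
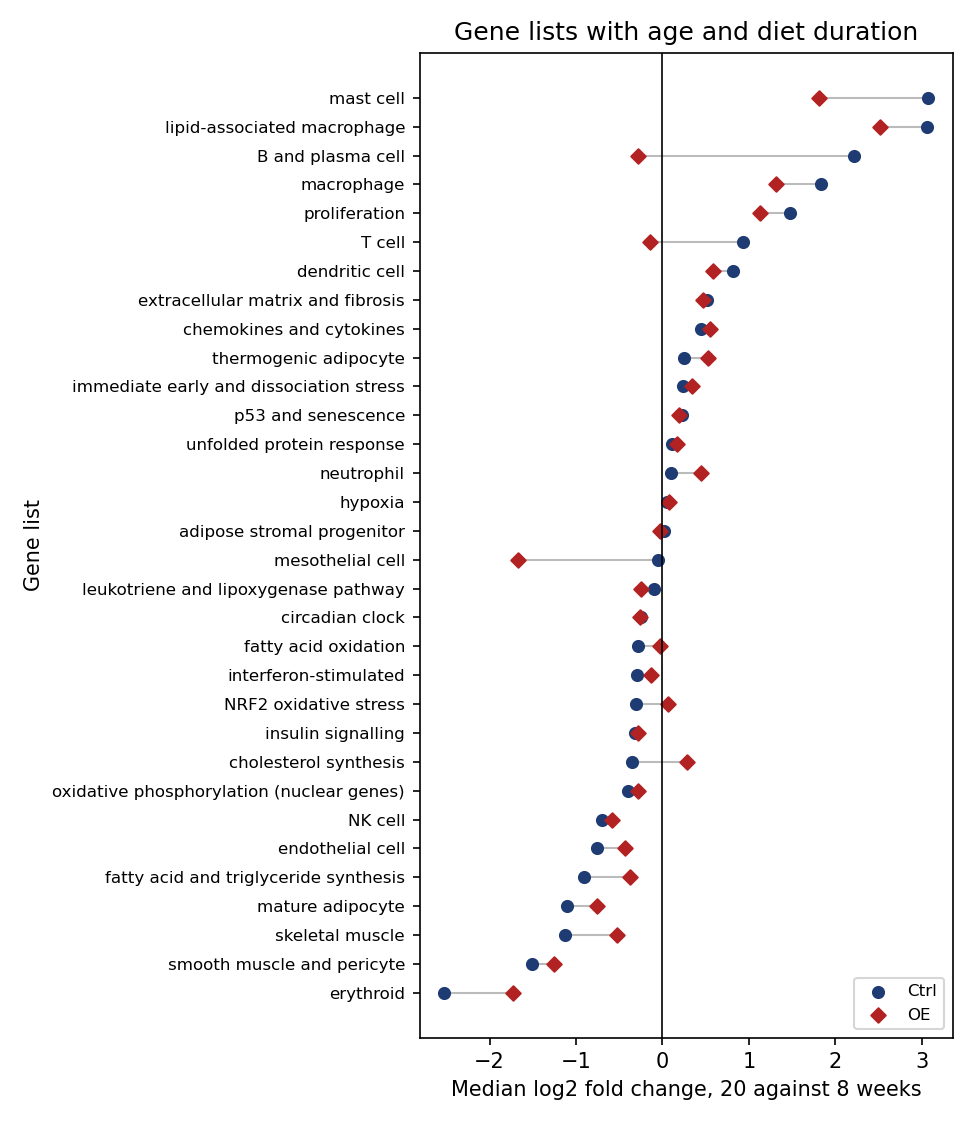
Median log2 fold change of the tested members of each fixed list except the epididymal epithelium list, 20 against 8 weeks, in Ctrl (circles) and in OE (diamonds). The lipid-associated macrophage list lies at 3.06 in Ctrl and 2.51 in OE, and the mature adipocyte list at −1.10 and −0.76.

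The comparison of 20 with 8 weeks in OE asked the same question in the presence of extra LTA4H. Macrophage genes again gave large rises, with the integrin gene Itgad higher by 4.91 ± 0.51 and the macrophage elastase gene Mmp12 (ID 17381, chromosome 9, 7344397 to 7360461) by 5.10 ± 0.91 (n = 4 in each group). Gpr50 rose by 6.30 ± 0.77, and Myh15 rose to 25.7 to 52.2 CPM from 0 in 3 of the OE_8wk libraries and 1.43 in replicate 2, without which the 8-week group is all at 0. Cfd fell 14.9-fold, Cyp2e1 fell 16.3-fold and Orm3 fell by 3.92 ± 0.40. Lta4h had a log2 fold change of −0.39 ± 0.14 without passing (adjusted p = 0.0522), and was called without Ctrl_8wk replicate 1 (0.0474) or OE_8wk replicate 2 (−0.53, 0.00366). It was also called without both libraries with epididymal transcripts (−0.53, 0.00398).

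In OE 2509 genes rose and 1902 fell, 23.0% of those tested, with 1160 and 635 changing more than 2-fold. With 2 surrogate variables 1617 rose and 1078 fell and 33 of 137 named gene results lost their call, and with glmTreat, which asks for more than 1.2-fold, 1565 rose and 851 fell and 22 lost it. Both settings lost Cysltr1, Mgst3 and Ndufa5, the first also Alox5ap and the second Ggt5. The size of the fall of Akr1b7, an aldo-keto reductase of the vas deferens (−10.99 ± 3.39, adjusted p = 0.0314), rested on OE_8wk replicate 2, a library with epididymal transcripts, at 4630 CPM against 1.39 to 25.9 in the other 3. It was −4.23 without that library, not called when it alone was left out (0.2004) but called without both libraries with epididymal transcripts (0.0352), and it was not called without any one of OE_20wk 1 to 4 (0.0574 to 0.0881). The purinergic receptor gene P2rx1 (−4.02 ± 1.21, 0.0283) likewise was at −1.92 without OE_8wk replicate 2, not called when it alone was left out (0.156) but called without both (0.00616), and not called without OE_20wk 2, 3 or 4 (0.0717 to 0.0849). The number of falling genes was 1036, 1221 and 1014 without OE_20wk replicates 2, 3 and 4, and 1134 and 1242 without OE_8wk replicates 3 and 4. With voom 3975 genes rose and 3673 fell.

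In the lipid-associated macrophage list 16 of 17 members rose in OE by either adjustment and 0 fell, with a median of 2.51, such as Ctsk (2.57 ± 0.27) and Itgax, the integrin CD11c (4.06 ± 0.48). In the macrophage list 14 of 20 rose and 3 fell (15 and 3 adjusted over the list alone), such as Cd68 (2.86 ± 0.40) and Cd84 (2.71 ± 0.39). Camera gave 1.33e-17 and 7.89e-08, and 0.354 and 0.413 with an estimated correlation. Proliferation genes rose in 27 of 28 cases by either adjustment, with Pcna at 1.10 ± 0.17 and Tpx2 at 1.62 ± 0.28 (4.00e-17, and 0.413 with an estimated correlation). Mast cell genes rose in 7 of 10 cases by either adjustment, including the tryptase gene Tpsb2 (2.02 ± 0.43), with 0.00103 by camera and 0.650 with an estimated correlation. Extracellular matrix genes rose in 7 of 31 cases and fell in 1 (8 and 1 adjusted over the list alone), including Mmp2 (1.41 ± 0.20) and Mmp14 (1.11 ± 0.18). Chemokines and cytokines rose in 9 of 34 cases (10 rising and 1 falling adjusted over the list alone), including Tgfb1 (1.21 ± 0.20). Camera gave 0.00119 and 0.00599, and 0.650 for each with an estimated correlation. The immediate early and dissociation list had 9 of 18 higher (9 and 1 lower adjusted over the list alone), including Atf3 (3.44 ± 0.43) and Fos (2.48 ± 0.34), at 0.00283 and 0.354 with an estimated correlation.

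Of the mature adipocyte list 10 of 20 fell in OE and 0 rose (12 and 1 adjusted over the list alone), including Retn (−2.97 ± 0.44) and the beta-3 adrenergic receptor gene Adrb3 (−2.64 ± 0.46), at 2.04e-06 and 0.650 with an estimated correlation. OE_20wk replicate 1 had the highest adipocyte list mean of the 20-week libraries. Fatty acid and triglyceride synthesis fell in 6 of 22 cases by either adjustment, with Thrsp at −2.12 ± 0.34 and Scd1 at −2.05 ± 0.34. Oxidative phosphorylation fell in 9 of 35 cases (14 adjusted over the list alone), with Cox6c at −0.49 ± 0.09 and Ndufa5 at −0.50 ± 0.11. Camera gave 0.00119 and 1.55e-05, and 0.650 for each with an estimated correlation. The mesothelial list fell in 9 of 12 cases (10 adjusted over the list alone), with a median of −1.68, including the mesothelial markers Upk3b (−1.75 ± 0.38) and Lrrn4 (−1.63 ± 0.36), at 1.26e-06 and 0.354 with an estimated correlation. OE_20wk replicate 3 had the lowest mesothelial mean of its group. All 6 erythroid genes fell by either adjustment, including Hbb-bt (−2.03 ± 0.49) and Hbb-bs (−1.92 ± 0.47), at 1.76e-04 and 0.566 with an estimated correlation. The endothelial list had 4 of 15 lower (9 adjusted over the list alone, camera 0.00119), and the smooth muscle list 6 of 12 lower and 1 higher (9 and 2, camera 0.0424), each 0.650 with an estimated correlation. Camera called 15 lists in OE, 8 higher and 7 lower, 0 of them with an estimated correlation, while fry called 9.

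The leukotriene list in OE had 4 of 19 higher and 3 lower over all genes, and 4 and 4 adjusted over the list alone (camera 0.761). Dpep2 rose by 2.49 ± 0.37, Alox5ap by 0.90 ± 0.22, Ggt5 by 0.54 ± 0.13 and Cysltr1 by 0.48 ± 0.16. Alox15, the 12/15-lipoxygenase, fell by 2.31 ± 0.44, Ltb4r1 by 1.58 ± 0.26 and Mgst3 by 0.72 ± 0.23. Cysltr1 was not called without any one of Ctrl_20wk 1 to 4, OE_20wk 2 to 4, Ctrl_8wk 2 or 4 or OE_8wk 2 to 4 (0.0509 to 0.135). Mgst3 was not called without any one of Ctrl_20wk 2, OE_20wk 2 to 4 or OE_8wk 1, 3 or 4 (0.0501 to 0.115).

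The change with age ran in parallel in the 2 genotypes. Across genes, which are not independent replicates, the age effect in Ctrl and in OE had a Pearson's r of 0.810 and a Spearman's rho of 0.856. Both genotypes shared 2303 rising and 1604 falling genes, where independent calls would share 493 and 405, and 0 genes were called in opposite directions. The fewer calls in OE than in Ctrl do not by themselves show a smaller response. Over genes called in Ctrl the median ratio of the OE to the Ctrl age effect was 0.714, but these genes were chosen for their change in Ctrl. Both depend on OE_20wk replicate 1, which lay between the ages. Without it 5786 genes were called with age in OE, against 4411 with all libraries. Without OE_20wk replicates 2, 3 or 4 the calls were 2866, 3272 and 2733. The ratio was not computed without replicate 1. The interaction called 0 genes with edgeR and 30 with DESeq2. Its median standard error was 0.299, against 0.213 for age in Ctrl and 0.212 in OE, so a smaller response in OE stays open.

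The transcripts of Rpl29 and Gm8210 divided the OE libraries, a pair singled out after their values were seen, though both were among the 10 smallest p-values at 8 weeks. Rpl29 (ID 19944, chromosome 9, 106428889 to 106431568) had 103 to 117 CPM in the 4 OE_8wk libraries and 123 CPM in OE_20wk replicate 4, against 175 to 240 CPM in the other 11 libraries. Gm8210, an Rpl29-related pseudogene, had 41.9 to 52.3 CPM in the same 5 libraries and 2.49 to 3.77 CPM in the others.

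**Figure D3:**
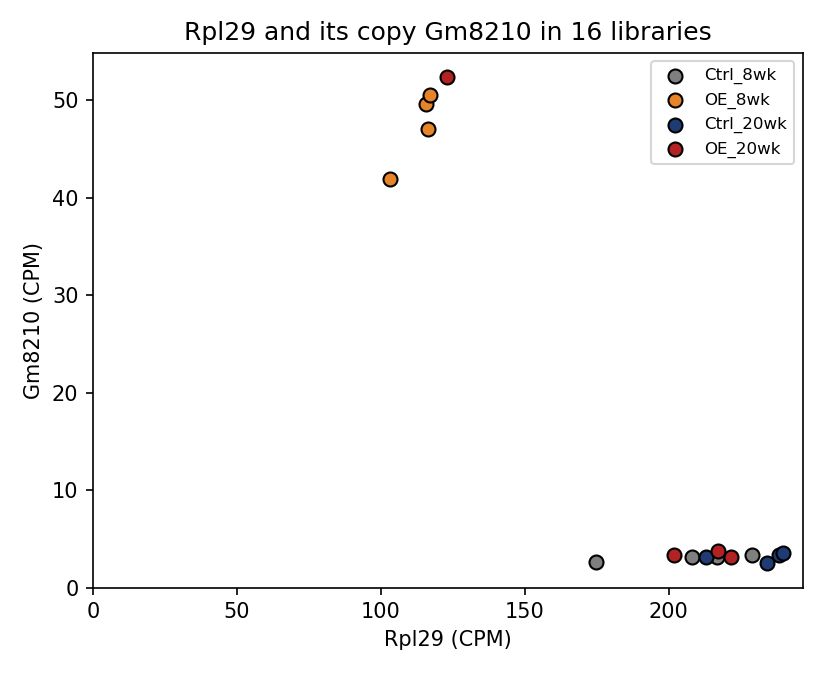
CPM of Rpl29 and of the pseudogene Gm8210 in each of the 16 libraries, by group. The 4 OE_8wk libraries and OE_20wk replicate 4 have 41.9 to 52.3 CPM of Gm8210 and 103 to 123 CPM of Rpl29, and the others 2.49 to 3.77 and 175 to 240 CPM.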

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

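Tests chosen only after their result was seen were those of clustering on chromosome 9, of closest genes counted once, of the genes beside Adipoq, of library depth and macrophage level in OE_20wk replicate 1, of epididymal transcripts, and of the 8-week calls with surrogate variables.

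Beside Lta4h, the genes called in OE averaged over both ages included pseudogenes, and the closest relatives of low-p pseudogenes lie together on chromosome 9, a search that left out Morf4l1b. Of the 8 tested pseudogenes with p under 0.001, 7 (87.5%) had their closest protein-coding gene on chromosome 9, between 86581371 and 110711606, but 3 of the 7 share Rpl29, and with each closest gene counted once 5 of 6 lay there against 28 of 549 for other pseudogenes (Fisher's exact p = 3.16e-06), and among other genes with p under 0.01 the odds ratio for chromosome 9 was 4.89 (Fisher's exact p = 1.66e-06, adjusted over 20 chromosomes 3.32e-05). A candidate explanation is a stretch of chromosome 9 from another mouse strain that travels with the transgene, whose reads would match the copies. Morf4l1-ps1, Gm7049 and Gm11868 were higher in all 8 OE libraries than in any Ctrl library, but they were picked as called higher in OE, so this lends no further support. A stretch of fixed length does not explain why Gm8210 stayed at 3.19 to 3.77 CPM in OE_20wk replicates 1 to 3. Of the closest genes on chromosome 9 only Rpl29 and Cyb5r4 had p under 0.05. Extra copies of the genes beside Adipoq, on chromosome 16, were argued against for the set, as only 1 of the 6 called genes, Eif4a2, lies there. For Eif4a2 they stay open. The 10 tested genes there, Eif4a2 itself included and Adipoq left out, had a median log2 fold change of 0.58, but 5 are small RNAs within Eif4a2. The median of the 4 left without these and Eif4a2 was 0.22, and these 4 were split. Rfc4, between Eif4a2 and Adipoq, was at 0.59 ± 0.11 (unadjusted p = 8.35e-05 and adjusted p = 0.134 with edgeR, not called). Gm30693 was at 0.64 ± 0.88, St6gal1 at −0.14 ± 0.12 and BC106179 at −0.74 ± 0.25. An effect of LTA4H on the called genes or those beside Adipoq was not tested and stays open, as does the inserted sequence itself, which was not analysed here. For Rpl29, Gm8210 and Gm13841, not called in that average, the 20-week values argue against the level of Lta4h alone. OE_20wk replicates 1 to 3 had 270 to 286 CPM of Lta4h and replicate 4 had 239. Yet Gm8210 had 3.19 to 3.77 CPM in replicates 1 to 3 and 52.3 in replicate 4. Gm13841 had 4.27 to 4.56 and 39.3 CPM, and Rpl29 202 to 222 and 123.

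OE_20wk replicate 1 lay between the ages, at a median position of 0.443 over 3372 of the 7853 genes called with age in Ctrl, those that changed by more than 0.5 log2 and in which Ctrl_8wk replicate 1 lay within 0.5 log2 of its group, with 0 for the Ctrl_8wk mean and 1 for the Ctrl_20wk mean, while the other OE_20wk libraries lay at 0.776 to 1.07. Its depth of 40.3 M counts argued against low depth, because the 5 shallower 20-week libraries all lay at 0.772 or higher. By position alone a mislabelled 8-week animal cannot be told apart from a late one, as OE_8wk replicate 2, a library with epididymal transcripts, reached 0.315. The other OE_8wk libraries lay at −0.0712 to 0.037. OE_20wk replicate 1 had 3.36 CPM of Gm8210 where the 4 OE_8wk libraries had 41.9 to 50.5. Among the largest age changes it lay outside the OE_8wk range for Itgad (98.5 against at most 7.11 CPM), Myh15 (25.7 against at most 1.43) and Cfd (530 against at least 3047). It lay within that range for Ggt1, Gstm7 and Dsp. Its macrophage list mean was 0.60 log2 CPM below the lowest other OE_20wk library. That list rose with age in Ctrl, so a library between the ages would have a low mean under any explanation. The mean therefore cannot decide whether fewer macrophages were among the cells sampled, which stays open. OE_20wk replicate 1 alone among 20-week libraries held Ggt1, at 12.4 CPM against at most 0.105. It had 34.9 CPM of Gstm7 and 12.8 of Dsp against at most 3.54 and 2.15. Other tissue in the sample thus stays open beside a slower response to the diet, neither of which was tested.

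The 8-week libraries differed within each genotype, and splits of them that ignored genotype called up to 727 genes. Whether hidden structure masks genotype effects stays open, because with 2 surrogate variables 7 genes were called averaged over both ages, as many as without them, but 6 rather than 4 at 8 weeks, and voom called 12 there. Epididymal duct tissue in Ctrl_8wk replicate 4 and OE_8wk replicate 2 would give high sums over the epididymal epithelium list. The lower of their summed CPM was 2420 against at most 166 in the other 8-week libraries, and 5 of the 14 list members passed the filter. The test was chosen after these sums were seen, so it lends no further support. Akr1b7, a gene of the vas deferens, had 7728.5 and 4629.7 CPM there against at most 25.85 in those other libraries, so that tissue stays open too. Ctrl_8wk replicate 1 and OE_8wk replicate 1, which stood apart, had the lowest sums at this age, 1.59 and 2.40 CPM. They had 0 CPM of Ggt1 where the other 6 had 7.25 to 39.1. Among these 6 Ggt1 did not follow the sums. It was 39.1 in OE_8wk replicate 4, with a sum of 19.7, and 25.0 and 19.3 in Ctrl_8wk replicate 4 and OE_8wk replicate 2. A smaller share of epididymal tissue in the libraries numbered 1 stays open by their sums, for which Ggt1 cannot stand. No biological explanation was tested.

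Other divisions of the same libraries gave the following counts. For genes at 20 weeks, 1 of 35 splits, the real one with 5 calls, gave as many, the highest other being 1. That is the smallest share that 35 splits allow, and the 5 calls include Lta4h, raised by design. Chance is thus made less likely but is not excluded. For age in Ctrl, 1 of 35 gave as many as the real 7853, the highest other being 1. For age in OE, 1 of 35 gave as many as the real 4411, the highest other being 2546. Each is again the smallest share possible, and splits that mix the ages can widen the spread within groups. Chance is thus made less likely for both but is not excluded. The split with 2546 set OE_20wk replicate 1 with OE_8wk replicates 1, 3 and 4, which points to a structure of the libraries. For genes at 8 weeks, 4 of 35 splits gave as many as the real 4, the highest other being 727, and chance cannot be excluded by the count alone. However, 3 of the 4 genes were also called at 20 weeks in other animals, where 0.00104 would be expected of independent calls. Of these, Lta4h was raised by design and carries no weight here, which leaves Gm11868 and Morf4l1-ps1. The split with 727 set Ctrl_8wk replicates 1 and 2 with OE_8wk replicates 1 and 3, and another, Ctrl_8wk replicates 1 to 3 with OE_8wk replicate 1, called 403, so the 8-week libraries hold a structure that does not follow genotype. For the average 6 of 100 drawn splits gave as many as the real 7, the highest other being 163, so chance cannot be excluded by the count alone. Of the 7 genes, Gm11868 and Morf4l1-ps1 were called at each age in different animals. The splits with 163, 120 and 114 calls all set Ctrl_8wk replicates 1 and 2 with OE_8wk replicates 1 and 3. For the interaction the real count was 0, which 100 of 100 splits must reach, so the splits decide nothing there. Its highest other, 53, and the 163 again point to structure. For list calls by camera chance could not be excluded in any contrast. At 8 weeks 11 of 35 splits reached the real 14, the highest other being 18, and at 20 weeks 25 of 35 reached 13, the highest other being 19. For age, 6 of 35 reached 18 in Ctrl, the highest other being 21, and 14 of 35 reached 15 in OE, the highest other being 18. For the interaction 9 of 100 reached 19, the highest other being 23, and for the average 91 of 100 reached 8, the highest other being 21.

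In 36 of 640 groups of 4 values 1 library lay far from the other 3, where chance flags about 1 in 20 groups, or 32. Among list means in log2 CPM these were oxidative phosphorylation in Ctrl_20wk replicate 3 (6.80), neutrophil in OE_20wk replicate 2 (1.35), mast cell in Ctrl_20wk replicate 4 (2.90), dendritic cell in OE_8wk replicate 3 (4.07), mesothelial in OE_20wk replicate 3 (2.12) and circadian clock in OE_8wk replicate 1 (4.19). Among genes named for OE against Ctrl, called or not, the CPM far from the other 3 were 2.36 for Gm11868 in OE_20wk replicate 1, 103 for Rpl29 in OE_8wk replicate 2 and 123 in OE_20wk replicate 4, and 12.7 for Zfp949 in Ctrl_8wk replicate 4. They were 30.3 for Gm13841 in OE_8wk replicate 2 and 39.3 in OE_20wk replicate 4, 2.59 for Gm8210 in Ctrl_8wk replicate 4 and 52.3 in OE_20wk replicate 4, and 8.05 for Lysmd2 in OE_8wk replicate 1. Among genes named for other comparisons they were, in OE_8wk replicate 2, 1.43 for Myh15, 5.71 for Cd22, 947 for Acta2, 25.8 for Ggt5, 70.3 for Sesn1 and 67.0 for Gsta3. In Ctrl_8wk replicate 1 they were 52.1 for Gpnmb, 2.47 for Itgad, 2.15 for Tpsb2 and 202 for Ccl9. In the other 8-week libraries they were 0 for Gpr50 and 87.7 for Ehhadh in OE_8wk replicate 3, 166 for Cpt1a in Ctrl_8wk replicate 4 and 77.9 for Ehhadh in Ctrl_8wk replicate 2. At 20 weeks they were 485 for C1qc and 30.9 for Mcpt4 in Ctrl_20wk replicate 4, 128 for Ndufa4 in Ctrl_20wk replicate 3, 50.8 for Dhcr7 in Ctrl_20wk replicate 1, 9.79 for Cysltr1 and 68.8 for Irf8 in OE_20wk replicate 1 and 22.2 for S100a8 in OE_20wk replicate 3.

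The genotype effect on 19 lists differed between 20 and 8 weeks by camera on the interaction, and for 0 of them with an estimated correlation, the lowest adjusted p being 0.124. The mean log2 fold change at 20 weeks exceeded that at 8 weeks by 0.38 for the leukotriene list (its median differed by −0.19), 0.43 for mature adipocyte, 0.44 for fatty acid and triglyceride synthesis, 0.22 for fatty acid oxidation, 0.10 for oxidative phosphorylation, 0.77 for thermogenic adipocyte, 0.64 for cholesterol synthesis, 0.28 for endothelial, 0.56 for smooth muscle and 0.80 for erythroid genes. The difference was −0.56 for macrophage, −0.58 for lipid-associated macrophage, −0.94 for T cell, −2.13 for B and plasma cell, −1.07 for mast cell, −0.35 for dendritic cell, −0.0938 for stromal progenitor, −1.04 for mesothelial and −0.30 for proliferation genes. Some of these rested on 1 library. As given above, the 20-week means of the mature adipocyte, B and plasma cell and mesothelial lists, which enter these differences, also shrank without 1 library. Without OE_20wk replicate 1 the difference was 0.0187 for the leukotriene and 0.0474 for the erythroid list, without OE_8wk replicate 2 it was −0.00728 for lipid-associated macrophage, and without Ctrl_8wk replicate 4 it was −0.18 for smooth muscle genes.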

How the results depend on the processing

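Settings added after seeing the data were the 2 surrogate variables and 3 sets of left-out libraries: the libraries numbered 1 at 8 weeks, the 2 with epididymal transcripts, and OE_20wk 1 with the libraries numbered 1 at 8 weeks. The 2 left out for epididymal transcripts had the highest sums, while Ctrl_8wk replicate 3, with a sum of 166 CPM, was kept. Lta4h was called higher in OE at both ages under every setting run. Counts of called genes stayed within 1.5 times with RLE or upper-quartile scaling, with no filter and with the stricter filter of 1 CPM in 4 samples. The cause was not tested for the following changes, except that fewer libraries were fitted where some were left out.

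With DESeq2, 10 genes were higher and 5 lower at 8 weeks, 40 and 20 at 20 weeks, 20 and 10 in the interaction, and 30 and 3 in the average. With voom there were 10 and 2 at 8 weeks, 14 and 6 at 20 weeks, and 3975 and 3673 with age in OE. With only the 2 groups compared, 7 were higher and 1 lower at 8 weeks. With glmTreat, which asks for more than 1.2-fold, 2647 fell with age in Ctrl, and 1565 rose and 851 fell in OE. With 2 surrogate variables 1083 rose and 675 fell in Ctrl, 1617 rose and 1078 fell in OE, and Alox12 reversed in Ctrl to 0.78. Without OE_20wk 1 and the libraries numbered 1 at 8 weeks, 3 genes were higher at 20 weeks, 3403 fell with age in OE and camera called 13 lists in the average. The labels do not say whether the replicate numbers pair animals. Deviations from the group mean were most alike between same-numbered libraries for 1 of 4 Ctrl animals at 8 weeks and 0 of 4 at 20 weeks. That 1 was replicate 1 at 8 weeks (r = 0.826 across genes). With the replicate block 4 genes were called at 8 weeks, 4 at 20 weeks and 6 in the average.

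Leaving out each animal in turn gave 4 to 8 genes higher and 0 to 1 lower at 8 weeks, 3 to 5 and 0 to 1 at 20 weeks, 6 to 10 and 0 to 1 in the average, and 0 to 0 and 0 to 3 in the interaction. It gave 2965 to 3840 rising and 2518 to 4318 falling with age in Ctrl, and 1719 to 3107 and 1014 to 2679 in OE. Lists called ranged from 7 to 18 at 8 weeks, 12 to 16 at 20 weeks, 16 to 19 with age in Ctrl, 14 to 16 in OE, 11 to 23 in the interaction and 7 to 14 in the average. The correlation of the genotype effects across genes ranged from −0.233 to 0.0434, reversing without Ctrl_8wk 3 (0.0434) or OE_8wk 1 (0.0168), and that of the age effects from 0.735 to 0.873; the latter was 0.931 over genes with a mean log2 CPM of at least 1.

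With an estimated correlation 1 list was called at 8 weeks, 0 at 20 weeks, 0 with age in Ctrl, 0 in OE, 0 in the interaction and 1 in the average. With fry it was 1, 0, 22, 9, 0 and 1. Without the libraries with epididymal transcripts camera called 9 lists at 8 weeks.

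Some lists reversed in camera when 1 animal was left out; camera sets a list against the other genes, so a small positive mean can count as lower. At 8 weeks the mature adipocyte mean ranged from −0.13 to 0.13 (0.13 without OE_8wk 2), oxidative phosphorylation from −0.13 to 0.0404 (0.0163 without Ctrl_8wk 2 and 0.0404 without OE_8wk 2), and extracellular matrix from 0.0158 (without Ctrl_8wk 4) to 0.27. Interferon ranged from −0.31 to 0.10 (without Ctrl_8wk 4) and proliferation from −0.16 to 0.15 (without OE_8wk 3). At 20 weeks erythroid ranged from −0.44 (without OE_20wk 1) to 0.56 and extracellular matrix from −0.11 (without OE_20wk 4) to 0.18. Oxidative phosphorylation ranged from 0.00993 to 0.18 in the interaction and from −0.0414 to 0.0454 in the average, where the values without OE_8wk 2 were 0.00993 and 0.0454. Without the libraries with epididymal transcripts the direction reversed at 8 weeks for the lipid-associated macrophage (−0.11, and 0.0847 in the interaction), extracellular matrix (−0.0420) and interferon (0.12) lists, and Pla2g4a reversed with age in Ctrl to 0.68. Without OE_20wk 1 and the libraries numbered 1 at 8 weeks, erythroid was −0.44 at 20 weeks, and macrophage (0.15) and chemokine (0.20) lists reversed in the average. Every alternative fixed beforehand was run. At this depth and spread 12.5% to 23.3% of simulated 1.5-fold changes were recovered. The adjusted p depends on how many genes change, and fewer were changed there than were called with age, 7853 in Ctrl and 4411 in OE. The shares thus do not give the power for age. Of the 3770 rising and 4083 falling genes in Ctrl, 1704 and 1964 changed more than 2-fold, so many smaller changes were called. For OE against Ctrl 12.5% were recovered at 8 weeks and 16.7% at 20 weeks. Only 4 and 5 genes were called there, so these shares may be too high. Most 1.5-fold changes between genotypes were thus not detectable.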

Other observations

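Stress programmes changed in part with age and diet duration. In the immediate early and dissociation list 7 of 18 genes rose and 2 fell in Ctrl (7 and 3 adjusted over the list alone), with Atf3 at 3.82 ± 0.44 and Fos at 2.70 ± 0.35 (camera adjusted p = 0.0581). In the p53 and senescence list 10 of 21 rose and 1 fell by either adjustment in Ctrl, with Gdf15, a stress-induced cytokine, at 3.06 ± 0.47, Sesn1 at 1.44 ± 0.16 and Igfbp3 at −1.07 ± 0.17, and 6 rose and 1 fell in OE, with Gdf15 at 2.24 ± 0.45. Camera gave 0.0307 and 0.0333, and 0.543 and 0.650 with an estimated correlation. Of the NRF2 oxidative stress list 7 of 16 fell and 3 rose in Ctrl by either adjustment, with Gsta3 at −2.85 ± 0.34 and Nqo1 at −1.11 ± 0.18 against Hmox1, the haem oxygenase, at 1.92 ± 0.24 (camera 0.250). In OE 6 fell and 1 rose (6 and 4 adjusted over the list alone), with Gsta3 at −2.38 ± 0.33 and Hmox1 at 1.64 ± 0.24 (camera 0.654). Of the hypoxia list 2 of 16 rose and 3 fell in Ctrl by either adjustment, with Car9 at 3.29 ± 0.54, Pdk1 at 0.67 ± 0.13 and Vegfa at −1.02 ± 0.21 (camera 0.927), and 1 rose and 2 fell in OE (0.860). Of the unfolded protein response list 4 of 19 rose, Calr at 0.48 ± 0.12 among them, and 2 fell in Ctrl by either adjustment (camera 0.337), and 2 rose and 1 fell in OE (1 and 1 adjusted over the list alone, camera 0.214). Interferon-stimulated genes showed 1 of 22 higher, Oas1a at 1.40 ± 0.33, and 2 lower, Isg15 at −0.97 ± 0.24 among them, in Ctrl (camera 0.270), and 1 higher and 0 lower in OE (camera 0.761).

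Lipid burning genes split in both genotypes. Of the fatty acid oxidation list 5 of 22 fell and 2 rose in Ctrl (4 and 2 adjusted over the list alone), with the peroxisomal gene Ehhadh at −1.47 ± 0.25 and the mitochondrial genes Cpt1a at 0.60 ± 0.08 and Hadha at 0.55 ± 0.09 (camera 0.192). In OE 3 rose and 2 fell (3 and 3 adjusted over the list alone), with Cpt1b at 1.64 ± 0.24 (camera 0.894). Of the thermogenic list 3 of 16 rose and 3 fell in Ctrl by either adjustment, with the elongase gene Elovl3 at 4.00 ± 1.01 and the coactivator gene Ppargc1a at −1.31 ± 0.36 (camera 0.653), and 4 rose and 0 fell in OE (5 and 1 adjusted over the list alone), with Otop1 at 2.93 ± 0.63 (camera 0.168). Insulin signalling genes showed 8 of 19 lower and 3 higher in OE (8 and 4 adjusted over the list alone, camera 0.0818), and cholesterol synthesis 4 of 23 higher and 1 lower (4 and 2, camera 0.140), with Dhcr7 at 1.38 ± 0.29.

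Camera called none of the other cell type lists of the following sentences, with its adjusted p in parentheses. Neutrophil genes showed 3 of 12 higher in Ctrl (camera 0.412) by either adjustment and 2 in OE (3 higher and 1 lower adjusted over the list alone, 0.468), with S100a8 at 1.41 ± 0.26 and 2.08 ± 0.27. NK cell genes showed 4 of 12 lower in Ctrl (1 adjusted over the list alone), with the granzyme gene Gzma at −2.30 ± 0.45 (camera 0.126), and 0 were called in OE with edgeR by either adjustment (0.131). In OE the T cell list showed 2 of 20 higher (1 adjusted over the list alone, camera 0.871), Il7r at 3.43 ± 0.54 among them, the B and plasma cell list 1 of 17 by either adjustment, Cd22 at 2.73 ± 0.49 (0.792), and the dendritic cell list 2 of 15 higher and 3 lower (7 and 3 adjusted over the list alone, 0.214). Stromal progenitor genes showed 5 of 16 higher and 2 lower in Ctrl by either adjustment, with the matrix gene Lum at 1.39 ± 0.15 and Pdgfra at 0.91 ± 0.17 (0.383), and 1 higher and 2 lower in OE (1 and 3 adjusted over the list alone, 0.871). Mesothelial genes showed 3 of 12 lower in Ctrl (2 adjusted over the list alone), the keratin gene Krt8 at −3.27 ± 0.89 among them (0.531). Skeletal muscle genes showed 1 of 11 higher and 4 lower in Ctrl by either adjustment, with Myh1 at −1.93 ± 0.54 (0.383), and 1 and 1 in OE (1 and 0 adjusted over the list alone, 0.761). Of the 5 epididymal epithelium genes tested, 2 were lower in Ctrl (3 adjusted over the list alone, 0.199) and 1 in OE by either adjustment (0.1999). The 2 libraries with the highest sums of these transcripts were both at 8 weeks, as was the next, Ctrl_8wk replicate 3 at 166 CPM. Circadian clock genes showed 4 of 15 lower in Ctrl by either adjustment, with Hlf at −2.00 ± 0.48 and Cry2 at −0.85 ± 0.21 (0.199), and 1 higher in OE by either adjustment (0.468). In Ctrl the median and mean of the thermogenic and neutrophil lists had opposite signs, as did those of the T cell and NRF2 lists in OE.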
